A study of Mus musculus with 7 samples.

How the data were processed

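RNA was measured in 7 libraries of mouse tumors that carry an exon 19 deletion of Egfr and were passaged under the skin of C57BL/6 mice. Per the labels' protocols, RNA was extracted from frozen tissue, ribosomal RNA was depleted, and directional libraries were prepared from total RNA. The labels give 1 library to each of 7 groups. The first group received vehicle and was sampled at day 3; its treatment field records no treatment. Gefitinib, a small-molecule inhibitor of the EGFR tyrosine kinase, was given for 3 or 14 days in the next 2 groups. The remaining 4 groups received gefitinib for 14 days and then, for 7 days, vehicle, DC101, 4H2 or both antibodies. For the vehicle group of day 21 too, the title names vehicle where the treatment field records no treatment, and the titles were followed. DC101 is an antibody against mouse VEGFR2, the receptor encoded by Kdr, and the series title names PD-1 as the other target, for which 4H2 is the antibody. How many animals entered each library is not given in the sources used here.

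The deposited values are TPM, a length-normalized transcript abundance, for 21892 gene symbols, rounded by the authors to 1 decimal, so that the smallest value above 0 is 0.1. The authors normalized each library to 1000000 over the listed genes. The build was GRCm38.p6, per the submitters' processing notes; the aligner, the counting tool and the annotation are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval can be given. Exact values of 0 are reported only as listed at 0, because all 13 mitochondrially encoded protein genes, which every cell uses, are listed at 0 in every library. 4188 symbols are listed at 0 in all 7 libraries. Gene symbols were matched to a RefSeq table of the same build for gene type and position, which gave a type to 21696 symbols and none to 196. Genes with near-identical copies, such as histone, hemoglobin, Sprr2a and H2-Q genes, carry uncertain values because the handling of shared reads is not given in the sources used here.

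With 1 library per group there is no replicate spread, and no p-value, standard error or test was computed. Each difference compares 2 libraries and has no replicate check. Differences were computed as log2((TPM + 1) / (TPM + 1)) for the 13997 genes with a mean TPM of at least 1 over the 7 libraries; the pseudocount of 1 makes the log2 difference of low genes smaller than the ratio of their TPM values. A gene was counted as higher or lower when it differed by at least 2-fold on that scale. There were 6 main comparisons and 4 secondary ones. Gefitinib at day 3 and at day 14 was set against vehicle at day 3, the 7 days after gefitinib against day 14 of gefitinib, and each antibody group against the vehicle group of day 21. The first 2 share a vehicle library and the 3 antibody comparisons share another. The comparison after gefitinib uses that day 21 vehicle library and the day 14 library of the second comparison, each with the opposite sign. Chance values of those libraries therefore enter several comparisons, and no overlap or correlation of gene calls between them was computed.

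47 gene lists with 649 entries were written before the data were examined: immune cell types, immune responses, stroma and vessels, tumor programmes, tissues that can lie beside a subcutaneous tumor, and RNA composition. 46 lists had at least 3 genes in the comparison. Each list is described by the median of its members, by the numbers of members at least 2-fold higher or lower, and by the percentile of its median among 10000 random lists of the same size drawn from the same 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5. This describes the libraries and is not a test of the treatment, because members of a list share a cell type and vary together.

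The genes named in the text come from a rule fixed before the data were examined. For each main comparison it takes the 8 highest and 8 lowest genes with a TPM of at least 10 in either library, leaving out predicted genes, ribosomal protein, histone, antigen receptor segment and noncoding genes. It adds, from each list that stands apart or was named as primary for the comparison, up to 4 members in the direction of the median and up to 2 in the other. Egfr, Kdr, Pdcd1, Cd274, Cd8a, Gzmb, Ifng and Vegfa are given in every library. Any other gene is marked as chosen after its values were seen.

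Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, a median-of-ratios rescaling over the 7340 genes with a TPM of at least 10 in every library, a rescaling without mitochondrial, histone, hemoglobin, ribosomal and small RNA genes and the 20 most abundant genes, the mean in place of the median, and lists without shared members. Chosen after seeing the data were the day 21 counts and rescaling without the 317 genes whose profile over the 7 libraries followed the skeletal muscle list (Pearson r of at least 0.95 across the libraries, used only to select genes). The procedure was tested on simulated data for 13997 genes with a log2 noise SD of 0.4. In the simulated comparison of gefitinib with vehicle at day 3, 98% of 4-fold and 100% of 8-fold genes passed the 2-fold limit in the right direction. In that comparison 4 of 4 shifted lists were recovered. The 4-fold and 8-fold genes were drawn from those with a mean TPM of at least 10, so these rates do not cover lower genes. They follow largely from the assumed noise and do not measure recovery in the real libraries. Among simulated pairs without the changed library, 3.44% of unshifted lists fell outside the percentiles. Simulated genes varied independently, so this rate does not carry over to real lists, whose members vary together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.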

Results

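Bulk RNA sequencing described subcutaneous mouse tumors of 7 treatment groups, with 1 library per group, as TPM values for 21892 genes. The sequencing depth behind these values is unknown. The tumors carry an exon 19 deletion of Egfr, the kind of mutation that makes lung adenocarcinoma sensitive to gefitinib. A day 3 vehicle library, libraries at day 3 and day 14 of gefitinib, and 4 libraries at day 21 were compared. The day 21 groups had received gefitinib for 14 days and then vehicle, DC101, 4H2 or both antibodies for 7 days. The series title places the question in the CD8 T cell response to joint blockade of PD-1 and VEGFR2 after EGFR inhibition. There were no replicates, so every difference below is a difference between 2 libraries.

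Of 13997 genes compared, between 589 and 6405 lay at least 2-fold apart in the 21 pairs of libraries. The closest pair was vehicle and DC101 at day 21 (589 genes, Spearman rho across genes 0.979), followed by 4H2 and the antibody combination (747 genes, rho 0.970). The most distant pair was vehicle at day 3 and 4H2 at day 21 (6405 genes, rho 0.655). The 12 skeletal muscle genes held 0.0300% of all TPM in the day 3 vehicle library, 0.225% and 0.393% at days 3 and 14 of gefitinib, 0.320% in the day 21 vehicle library, 1.80% with DC101, 8.51% with 4H2 and 8.50% with the combination. The 15 epithelial keratin and junction genes held 0.459%, 0.153%, 0.234%, 0.854%, 0.570%, 0.00527% and 0.0439% in the same order. Reference genes such as Actb and Gapdh did not stand apart in any of the 6 main comparisons, with list medians between -0.52 and 0.33.

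Egfr (chromosome 11, 16752203 to 16913907, in GRCm38.p6) was at 629.8 TPM in the day 3 vehicle library, 499.3 and 438.7 at days 3 and 14 of gefitinib, 446.7 in the day 21 vehicle library and 537.8 with DC101, against 19.4 with 4H2 and 48.3 with the combination. Kdr (chromosome 5, 75932827 to 75979072), which encodes VEGFR2, was at 7.5, 22.9, 18.6, 19.6, 11.4, 10.7 and 9.3 TPM in the same order of libraries. Pdcd1 (chromosome 1, 94038305 to 94052553), which encodes PD-1, was at 0.8, 11.7, 85.5, 27.5, 15.8, 40.6 and 31.4 TPM, and Cd274 (chromosome 19, 29362107 to 29388095), which encodes its ligand PD-L1, at 7.6, 45.5, 74.2, 36, 23.1, 88.9 and 83 TPM. Cd8a (chromosome 6, 71373427 to 71379171) was at 0.7, 10.6, 58.8, 30.6, 21.1, 56 and 34.2 TPM. Gzmb (chromosome 14, 56258836 to 56262334), a cytotoxic granule protease, was at 3.1, 31.6, 21.1, 9.1, 5.5, 15.3 and 8.3 TPM, and Ifng (chromosome 10, 118441046 to 118445894) was listed at 0 in the day 3 vehicle library and at 4.3, 14.4, 10.1, 4.1, 14.5 and 6 TPM in the others. Vegfa (chromosome 17, 46016993 to 46032377) stayed between 45.7 and 75.3 TPM.

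**Figure D1:**
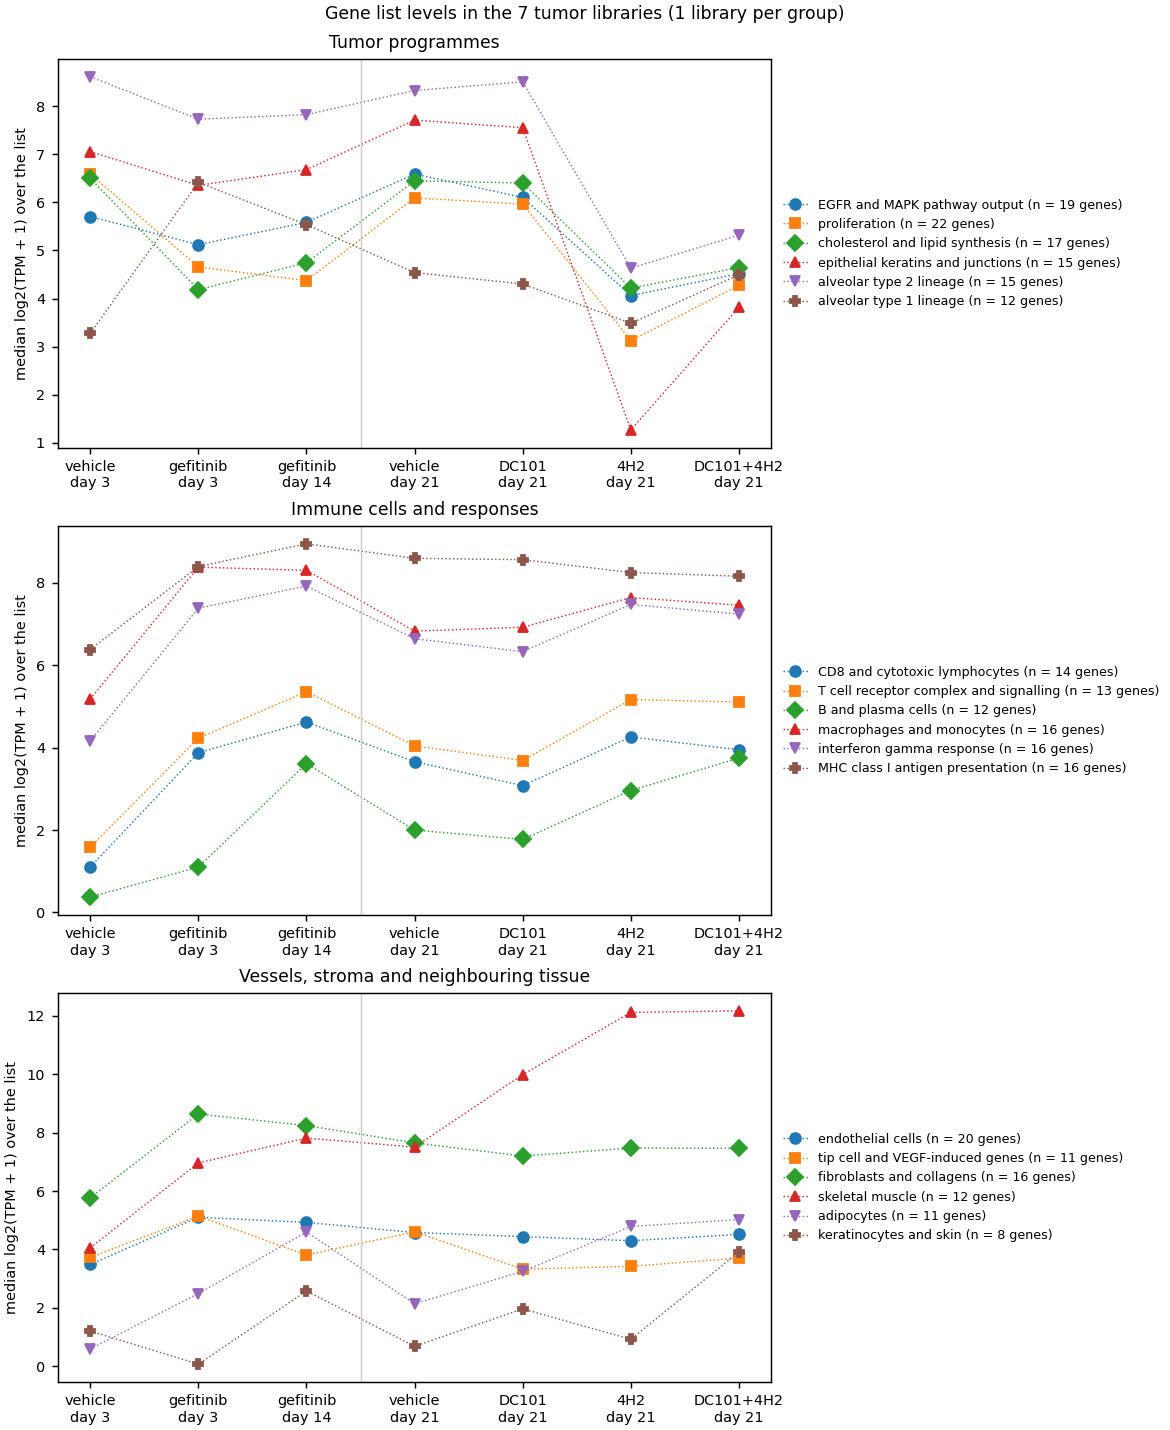
Median log2(TPM + 1) over the measured members of 18 gene lists (y axis) in each of the 7 libraries (x axis, 1 library per group; dotted lines only join the points of a list). The epithelial list lay at 7.71 in the day 21 vehicle library and 1.26 in the 4H2 library, while the skeletal muscle list lay at 7.51 and 12.12.

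After 3 days of gefitinib, against vehicle at day 3, EGFR and MAPK output, proliferation, cholesterol synthesis and epithelial genes were lower, and most immune and stromal lists higher. Targets and feedback regulators of EGFR and MAPK signalling had a list median of -0.98 (percentile 0): 9 of 19 were at least 2-fold lower and none higher. Etv4, a transcription factor induced by ERK, was at 22.1 against 163.1 TPM, Epha2 at 33.8 against 96.8 and the ERK phosphatase gene Dusp4 at 56.6 against 173.2, whereas Myc was at 68.6 against 42.6. The proliferation list had a median of -1.93 (percentile 0), with 19 of 22 genes lower; the mitotic regulators Aurka, Cdc20 and Bub1 were at 10.6, 30.1 and 3.7 against 67.6, 172 and 32.8 TPM. Cholesterol and lipid synthesis genes had a median of -1.87 with 13 of 17 lower, among them Sqle (6.7 against 89.6 TPM) and Idi1 (5.5 against 76.6). The proliferation and cholesterol medians lay near the epithelial median of -1.69. Whether a smaller share of epithelial cells lowered these 2 lists was not tested.

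The epithelial list was lower in the same comparison (median -1.69, 12 of 15 lower), with Epcam at 80.9 against 571.2 TPM and Cldn4 at 2.8 against 26.9, but Cldn18 at 108.9 against 62.1. Alveolar type 2 genes, which mark the surfactant-producing cells of the lung, had a median of -1.15 with 10 of 15 lower; Lamp3 was at 37.2 against 281.2 TPM and Sftpb at 2955 against 8418. Alveolar type 1 genes, which mark the flat gas-exchange cells, had a median of 1.62: 7 of 12 were higher and 1 lower, with Ager at 1254 against 269.9 TPM, Hopx at 125.6 against 11.5 and Sec14l3 at 93.4 against 6.5. Hypoxia and glycolysis genes had a median of -0.78 (5 of 16 lower), and histone genes -1.73 (12 of 12 lower). The lowest genes included Scgb3a1, listed at 0 against 100.6 TPM, Cd177 (1.8 against 280.5), Lce3f (0.7 against 144), Dlk1 (12.8 against 822.5) and the secretory genes Dcpp3 (3.2 against 326.4) and Dcpp1 (0.6 against 95.2).

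Antigen presentation and interferon genes were higher at day 3 of gefitinib. The MHC class I list had a median of 2.26 (14 of 16 higher, none lower), with B2m at 7259 against 1056 TPM and Nlrc5, its transcriptional activator, at 69 against 10.3. The interferon gamma list had a median of 3.23 (15 of 16 higher), including the T cell attracting chemokine genes Cxcl9 (299 against 11.8 TPM) and Cxcl10 (167.1 against 13.8), and the type I interferon list 2.71 (16 of 16), including Irf7 (432.4 against 23.3). MHC class II genes had a median of 1.48 (9 of 10 higher). Lymphocyte lists were higher too: 13 of 14 CD8 and cytotoxic genes (median 2.88), 13 of 13 T cell receptor genes (2.60), 9 of 9 NK cell genes (2.74) and 11 of 12 checkpoint genes (2.04). Gzma was at 58.5 against 3.4 TPM, Nkg7 at 54.6 against 3.1, Cd3e at 52.2 against 5.3 and Xcl1 at 44.7 against 1.4. B and plasma cell genes did not stand apart (median 0.77, percentile 96.2).

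Several myeloid and stromal lists were also higher at day 3 of gefitinib. Neutrophil genes (median 0.92, percentile 95.0), alternative macrophage activation genes (0.39, 84.9) and lymphatic and venule genes (1, 96.3) did not stand apart. Macrophage and monocyte genes had a median of 3.20 (15 of 16 higher), with Adgre1 at 385.7 against 31.2 TPM and Fcgr1 at 133.8 against 10. The Fc receptor gene Fcgr4 was among the 8 highest at 243.3 against 10.2. Fibroblast genes had a median of 2.91 (15 of 16 higher): Col1a1 was at 10262 against 943.5 TPM, and Lum at 191.9 against 7.7. The matrix genes Mfap4 (415.3 against 14.1), Ogn (63 against 1.6), Col8a2 (161.4 against 5.8) and Itgbl1 (76.4 against 0.6) were among the 8 highest genes. Mesenchymal transition genes had a median of 2.28 (12 of 14 higher, none lower). Endothelial genes had a median of 1.90 (16 of 20 higher) and pericyte and smooth muscle genes 1.79 (9 of 11). Skeletal muscle genes moved with these groups, at a median of 2.91 with 12 of 12 higher (Mb 64.3 against 5 TPM), as did adipocyte genes (1.42, 8 of 11). In all, 2904 genes were higher and 2013 lower. The median of all genes was -0.09, and 0.01 under median-of-ratios scaling, which turned the direction of none of the lists in this comparison.

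At day 14 of gefitinib, against the same day 3 vehicle library, T and B cell, fibroblast and endothelial genes were higher, and EGFR and MAPK output, proliferation, cholesterol synthesis and epithelial genes lower. The CD8 and cytotoxic list had a median of 3.69 (percentile 100; 13 of 14 higher), with Cd8a at 58.8 against 0.7 TPM, Nkg7 at 178.9 against 3.1 and Ccl5 at 776.6 against 26. Pdcd1 was at 85.5 against 0.8 TPM, Tigit at 53.9 against 1.5 and Lag3 at 99.7 against 6.1, within a checkpoint list of which 12 of 12 genes were higher (median 3.24). B and plasma cell genes had a median of 2.72 (12 of 12 higher); Jchain, which joins secreted antibody multimers, was the highest gene of the comparison at 288.8 against 0.4 TPM, and Cd79a was at 27.1 against 0.2. The venule and lymphatic list (median 2.14, 6 of 9 higher) held Ccl21a, a chemokine gene that draws lymphocytes from vessels, at 46 TPM and listed at 0 in vehicle. MHC class I genes had a median of 2.79 (15 of 16 higher), with Tap1 at 482.3 against 55.5 TPM, MHC class II genes 2.39 (10 of 10) and interferon gamma genes 3.90 (15 of 16), with Gbp4 at 97.1 against 3.7 TPM.

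EGFR and MAPK output genes had a median of -0.97 at day 14 (percentile 0; 9 of 19 lower, 2 higher): Etv4 was at 47 against 163.1 TPM and Epha4 at 10.9 against 45, while Ier3 was at 64.6 against 24.1 and Dusp5 at 37.8 against 17.2. The epithelial list lay at -0.96 beside it (7 of 15 lower). Proliferation genes had a median of -2.09 (20 of 22 lower) and cholesterol genes -1.53 (12 of 17 lower), with the desaturase gene Scd1 going the other way at 286.1 against 26.2 TPM. Histone genes were at -2.02 (12 of 12 lower) and ribosomal protein genes at -1.06 (11 of 20 lower) beside them, and immediate early and heat shock genes at 0.82. Mesenchymal transition genes had a median of 2.08 (9 of 14 higher, none lower). The alveolar type 1 list was higher (median 1.34; Aqp5 669 against 137.8 TPM), and the type 2 list lower (-1.28), although Sftpd was at 917.8 against 432. Receptor tyrosine kinase genes other than the ErbB family had a median of 1.07 (8 of 15 higher, 5 lower). Axl was at 624.7 against 46.6 TPM and Ros1 at 8.6 against 79.2. Whether tumor or stromal cells gave the RNA of the kinase and mesenchymal transition lists was not tested. Fibroblast genes had a median of 2.53 (15 of 16 higher) and endothelial genes 1.40 (14 of 20 higher). Macrophage genes had a median of 3.39, with Ly6c2 at 271.4 against 7.2 TPM. The alternative activation list was lower (median -1.25; 6 of 10 lower, 4 higher), with Arg1 at 27.4 against 142.4 and Retnla at 1710 against 167.2. Skeletal muscle (3.85, 12 of 12 higher), adipocyte (3.06, 9 of 11; Cfd 376.8 against 7 TPM) and skin genes (1.86, 5 of 8; Krt71 30.2 against 3.8) were higher in the same library. In all, 3173 genes were higher and 1780 lower. No vehicle library of day 14 was used here, so days in the animal and gefitinib are not separated.

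Set directly against day 3 of gefitinib, the day 14 library had 682 genes higher and 376 lower. B and plasma cell genes stood 2.10 higher (10 of 12 at least 2-fold), T cell receptor genes 1.15 (11 of 13) and CD8 genes 1.04 (8 of 14), whereas the NK list was at -0.39, tip cell and VEGF-induced genes were at -1.52 (8 of 11 lower) and fibroblast genes at -0.94 (7 of 16 lower). Muscle genes were 0.93, adipocyte genes 1.69 and skin genes 1.88 higher in this pair. Erythroid genes were at -2.45 (4 of 5 lower) and ribosomal protein genes at -0.42. The median of all genes was 0.11.

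In the library taken 7 days after the end of gefitinib, against day 14 of gefitinib, EGFR and MAPK output, proliferation, cholesterol synthesis and epithelial genes were higher, and most immune lists lower. EGFR and MAPK output had a median of 0.75 (5 of 19 higher, none lower), with Dusp6 at 338 against 125.5 TPM, Etv4 at 145.7 against 47 and Epha4 at 54.7 against 10.9. Proliferation genes had a median of 1.51 (17 of 22 higher; Cdc20 114.9 against 23 TPM), cholesterol genes 1.56 (11 of 17) and epithelial genes 1.46 (12 of 15; Krt8 1731 against 341.1 and Krt19 1315 against 186.7). The EGFR ligand genes Areg and Hbegf were at 179.1 and 61.5 against 27 and 18.7 TPM. Histone genes were at 0.95 (5 of 12 higher) beside them. Other receptor tyrosine kinase genes and mesenchymal transition genes were both lower (-0.47 each), close to the fibroblast median of -0.49. Alveolar type 1 genes (-0.30) did not stand apart. Genes of gastric and gut lineages had a median of 0.72 (3 of 7 higher): Hnf4a, a transcription factor of gut and liver epithelium, was at 52.3 against 2.2 TPM, and Gkn2, a gastric mucosa gene, at 109.7 against 2.6. Others among the 8 highest were Sprr2a1 and Sprr2a2 (53.6 and 54 against 0.2 TPM), Gzme (158.9 against 3.1), Vil1 (53.3 against 1.3) and Crct1 (172.3 against 8).

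The CD8 list was lower 7 days after gefitinib (median -0.93, percentile 0; 6 of 14 lower, none higher), with Ccl5 at 280.8 against 776.6 TPM and Tbx21, a transcription factor of cytotoxic and type 1 helper cells, at 6.3 against 25.4. T cell receptor genes had a median of -1.32 (13 of 13 lower), B and plasma cell genes -1.46 (11 of 12; Jchain 42.1 against 288.8 TPM), macrophage genes -1.11 (11 of 16), mast cell genes -2.34 (5 of 7; Cpa3 1.4 against 13.7) and interferon gamma genes -0.88 (6 of 16; Cxcl9 111.8 against 511.9). MHC class I genes were at -0.48 with 1 of 16 lower by 2-fold. Neutrophil genes were at -0.01, and inflammatory cytokine and chemokine genes at -0.34. Cbr2, a carbonyl reductase gene, was the lowest gene at 42.3 against 2398 TPM, and Retnla was at 47.5 against 1710. Adipocyte genes (-1.55, 8 of 11 lower) and hair genes (Tchh 1 against 41.8 TPM, Krt71 0.6 against 30.2) were lower in the same library, and skeletal muscle genes were at -0.33. In all, 1063 genes were higher and 1093 lower. No day 21 library under continued gefitinib was used here, so the end of gefitinib and 7 more days in the animal are not separated.

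Against the day 3 vehicle library, the day 21 vehicle library did not stand apart in EGFR and MAPK output (median 0.12, percentile 69.4), cholesterol synthesis (-0.03) or epithelial genes (0.26), while proliferation was at -0.55 and stood apart. It also stood apart in MHC class I (2.29, 15 of 16 higher), T cell receptor (2.44, 12 of 13), macrophage (2.10, 14 of 16) and skeletal muscle genes (3.47, 12 of 12). The counts were 2130 genes higher and 433 lower. Past gefitinib and days in the animal are not separated in this pair either.

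DC101 for 7 days, against vehicle at day 21, came with lower blood vessel and fibroblast genes, while the lymphatic and venule list was higher. The endothelial list had a median of -0.29 and stood apart, with 18 of 20 genes lower than in vehicle but none by 2-fold: Cdh5, the cadherin of endothelial junctions, was at 54.5 against 91.4 TPM, Kdr at 11.4 against 19.6 and Emcn at 10.1 against 17.3, while Vwf was at 29.5 against 23.9. Tip cell and VEGF-induced genes had a median of -0.57 (percentile 0; 3 of 11 lower, 1 higher), with Dll4 at 5.4 against 14 TPM, Nid2 at 12.7 against 35.2 and Apln at 121.3 against 53.8. The fall was not particular to DC101. Against the same vehicle library this list was at -0.60 with 4H2 (3 of 11 lower) and -0.55 with the combination (2 of 11 lower), without standing apart. Pericyte and smooth muscle genes were at -0.42 with DC101 (Acta2 65.7 against 188.2 TPM). Among the 8 lowest genes were Krt17 (22.2 against 113.2 TPM), Igfbp3 (27.9 against 120.4), Prnd (5.4 against 27), Pyy (1.9 against 13.8), Moxd1 (4.4 against 24.6) and Slpi (14 against 57). Fibroblast genes were at -0.32, with none of 16 apart by 2-fold, close to the endothelial median. VEGF ligands and receptors were at -0.45 (2 of 10 lower), but at 0.13 with a mean TPM of at least 5 and at 0.32 without members of other lists. The lymphatic and venule list stood apart upward (median 0.31; 1 of 9 higher and 1 lower by 2-fold), with Ccl21a at 22.2 against 10.5 TPM, Lyve1 at 8 against 4.7 and Flt4 at 3.1 against 8.2. The hypoxia list also stood apart upward with a median of 0.20 and no member 2-fold higher (Egln3 15.8 against 8.9 TPM). That rise was not particular to DC101 either. Against the same vehicle library the list stood apart with the combination, at 0.44 (percentile 99.5, 3 of 16 higher and 1 lower). With 4H2 the hypoxia list was at 0.27 (percentile 97.1) and did not stand apart.

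**Figure D2:**
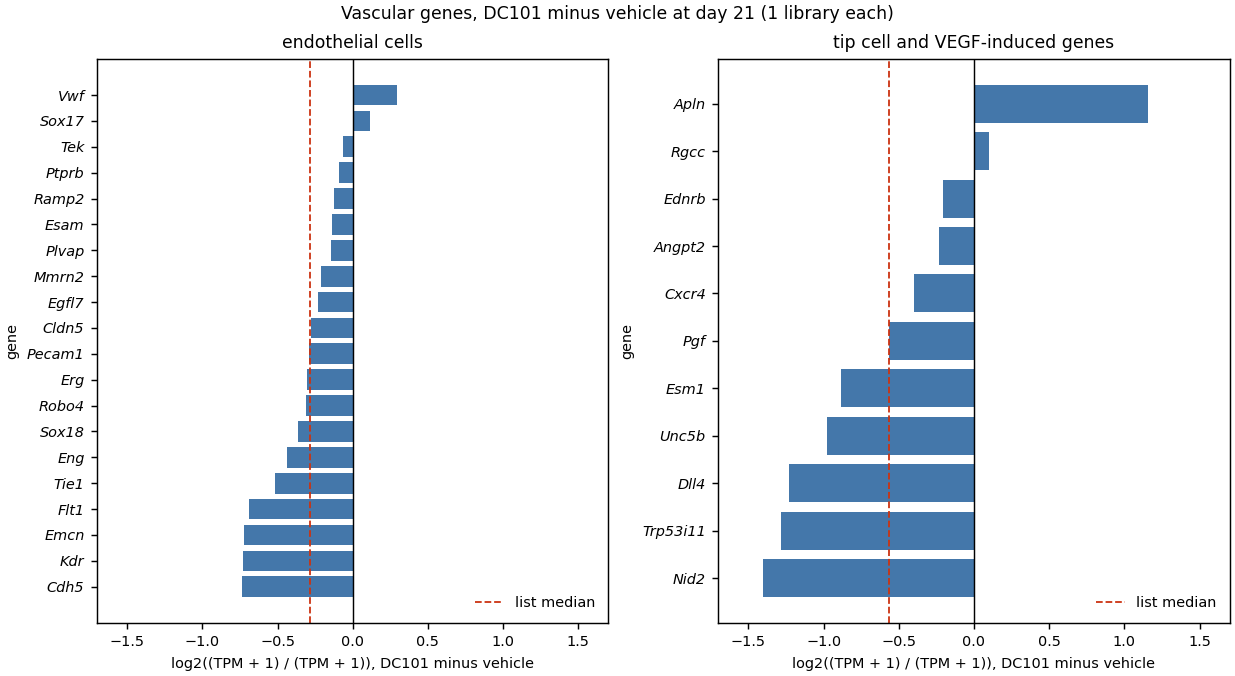
Log2((TPM + 1) / (TPM + 1)) of DC101 minus vehicle at day 21 (x axis) for each of 20 endothelial and 11 tip cell and VEGF-induced genes (bars, y axis; 1 library each, no error can be drawn), with the list medians of -0.29 and -0.57 as dashed lines. Cdh5 lay lowest in the endothelial list at -0.74, and Nid2 lowest and Apln highest in the other at -1.40 and 1.16.

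Several lymphocyte lists were lower with DC101 alone: CD8 and cytotoxic genes had a median of -0.54 (percentile 0; 2 of 14 lower by 2-fold, none higher; Gzma 2 against 5.8 TPM, Ifng 4.1 against 10.1), T cell receptor genes -0.34, NK genes -0.52 and interferon gamma genes -0.39 (Cxcl9 60.8 against 111.8). No member of the T cell receptor, NK and interferon gamma lists was 2-fold apart, and 3 of 9 NK genes were higher than in vehicle. Naive and memory lymphocyte genes (0.09) and B and plasma cell genes (-0.22) did not stand apart. The epithelial list was at -0.39 (Cldn4 94.1 against 209 TPM, Epcam 406.7 against 332.3) and the alveolar type 2 list at 0.18 (Sftpc 4900 against 2429). Skeletal muscle genes were the highest of the comparison, at a median of 2.61 with 12 of 12 higher: Myh4 was at 1619 against 176.5 TPM, Ckm at 2416 against 344.9, Pvalb at 690.9 against 80.7, Actn3 at 440.3 against 58.7 and Mstn at 20.2 against 1. Adipocyte genes were at 1.21 (8 of 11 higher) and skin genes at 0.95. Of 435 genes higher and 154 lower, 216 and 154 were counted without the genes that follow muscle. The lower count was 93 with a mean TPM of at least 5, 51 with a pseudocount of 5 and 296 with a pseudocount of 0.1, and the higher count 203 with a pseudocount of 5.

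With 4H2, against vehicle at day 21, epithelial genes were lower throughout and lymphocyte genes higher. All 15 epithelial genes were lower (median -6.44): Krt8 was at 6.6 against 1731 TPM, Krt18 at 12.1 against 2051, Krt19 at 8.4 against 1315 and Cldn3 at 2.8 against 815.2. Alveolar type 2 genes had a median of -5.27 (14 of 15 lower; Sftpb 76.2 against 9561 TPM, Nkx2-1 1.1 against 238.3), proliferation genes -2.77 (21 of 22; Cdk1 1 against 32.9), EGFR and MAPK output -1.91 (15 of 19; Etv4 3.5 against 145.7), ErbB receptors and ligands -3.57 (7 of 9; Areg 1.5 against 179.1) and cholesterol genes -1.91 (15 of 17). Histone genes were at -2.37 (12 of 12 lower) beside them. The secretory gene Wfdc2 (5.1 against 899.7 TPM) was among the 8 lowest, and Gzme and Tmem254c were listed at 0 against 158.9 and 195.3 TPM. Skeletal muscle genes stood at a median of 4.87 (12 of 12 higher; Ckm 11345 against 344.9 TPM, Myh4 7684 against 176.5), as did the muscle genes Mstn (130.2 against 1), Casq1 (1435 against 35.6) and Car3 (6934 against 158.6), and adipocyte genes at 2.32 (9 of 11).

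In the same 4H2 library, 5 of 14 CD8 and cytotoxic genes were at least 2-fold higher and none lower (median 0.76, percentile 99.9). Ccl5 was at 1332 against 280.8 TPM, Tbx21 at 21.6 against 6.3 and Gzmk at 14.2 against 5.1, Cd8a at 56 against 30.6, Gzmb at 15.3 against 9.1 and Prf1 at 13.9 against 16.6. T cell receptor genes had a median of 1.19 (10 of 13 higher; Lat 90.4 against 24.8 TPM, Cd2 101.1 against 33.5), B and plasma cell genes 1.05 (9 of 12; Ms4a1 3.7 against 0.5) and dendritic cell genes 0.90 (5 of 12; Clec9a 23.5 against 6.3, but Ccl17 1.5 against 16.1). The interferon gamma list had a median of 0.70 (percentile 99.9; 7 of 16 higher), with Cxcl9 at 334.5 against 111.8 TPM and Gbp4 at 88.9 against 30. The checkpoint list had a median of 0.75, with the PD-1 ligand genes Cd274 at 88.9 against 36 and Pdcd1lg2 at 72.5 against 23.8, and Entpd1 at 62.6 against 99.1. Macrophage genes had a median of 0.58 (4 of 16 higher; Lyz2 7571 against 2953 TPM). The neutrophil list, with 7 of 15 genes measured, had a median of -1.28 (4 lower and 2 higher by 2-fold). It was led by Lcn2 at 1 against 267.6, with Csf3r at 50.4 against 19.6. Epithelial genes were lower in the same library, and which cells gave the Lcn2 RNA was not tested. The list median is therefore no measure of neutrophil number. MHC class I (-0.04), endothelial (-0.21) and fibroblast genes (-0.16) did not stand apart; all 3 medians turn positive under median-of-ratios scaling, at 0.21, 0.03 and 0.09. Muscle and adipocyte genes were higher beside each of these groups, by the medians given.

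The 4H2 library had 1525 genes higher and 2791 lower than vehicle, which is 35.3% higher among those apart. The median of all genes was -0.21 (and -0.17 for the combination below), and under median-of-ratios scaling the counts were 2103 and 2186, or 49.0% higher. Without the genes that follow muscle, 1222 were higher and 2791 lower. Leaving out genes chosen for following muscle, which was higher, could hardly alter the lower count. Relative to the median of all genes, the CD8 and interferon gamma medians were further above the rest, and the endothelial and fibroblast medians lay close to it.

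With DC101 and 4H2 together, against vehicle at day 21, epithelial genes were lower and T cell receptor, B cell and naive lymphocyte genes higher. The epithelial list had a median of -3.98 (15 of 15 lower; Krt8 72.7 against 1731 TPM, Cldn18 3.7 against 170.8), alveolar type 2 genes -3.60 (13 of 15; Sftpc 144.6 against 2429), proliferation genes -1.79 (20 of 22) and EGFR and MAPK output -1.46 (14 of 19). Histone genes were at -1.22 (9 of 12 lower) beside them. T cell receptor genes had a median of 1.06 (8 of 13 higher; Cd2 83.9 against 33.5 TPM), B and plasma cell genes 1.66 (10 of 12; Cd79a 33.4 against 7.5) and naive and memory lymphocyte genes 1.16 (6 of 10; Lef1 14.5 against 1.8, Tcf7 46.5 against 9.5). CD8 and cytotoxic genes did not stand apart (median 0.20, percentile 94.4; 3 of 14 higher, none lower): Ccl5 was at 902.3 against 280.8 TPM, Cd8a at 34.2 against 30.6, Gzmb at 8.3 against 9.1 and Ifng at 6 against 10.1. The interferon gamma list stood apart (median 0.43, percentile 99.6; 3 of 16 higher; Gbp4 86.6 against 30 TPM), but not with the mean over members (0.43, percentile 96.3). Type I interferon genes were lower (-0.67, percentile 2.08, 2 of 16 by 2-fold), with Isg15 at 41.5 against 86.6 TPM and Oas3 at 12.2 against 38.4. Their median was -0.44 under median-of-ratios scaling.

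Endothelial genes in the combination library had a median of -0.17 (percentile 58.0; 3 of 20 lower), turning to 0.06 under median-of-ratios scaling, with Kdr at 9.3 against 19.6 TPM, Cdh5 at 43.5 against 91.4, Emcn at 7.7 against 17.3 and Ramp2 at 54.5 against 31.4. Among macrophage genes (median 0.35), Cd163 was at 19.9 against 3.3 TPM, and in the alternative activation list (0.64) Retnla was at 413.8 against 47.5 and Folr2 at 52.9 against 7.6, with Arg1 at 2.4 against 18. Beside these groups, skeletal muscle genes had a median of 4.90 (12 of 12 higher; Myh2 1531 against 28.4 TPM), adipocyte genes 2.78 (11 of 11) and skin genes 2.48 (6 of 8). Hair shaft and follicle genes were among the 8 highest, with Tchh at 220 against 1 TPM, Krt71 at 172 against 0.6 and Krt27 at 79.4 against 0.2, and Krtap8-1, Krtap11-1 and Krtap7-1 at 84.8, 68.5 and 66.3 TPM and listed at 0 in vehicle. In all, 1627 genes were higher and 2364 lower (40.8% higher), 1326 and 2364 without the genes that follow muscle, and 2139 and 1765 (54.8% higher) under median-of-ratios scaling.

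Set directly against 4H2 alone, the combination library had 683 genes higher and 64 lower. Epithelial genes were 2.45 higher (13 of 15 by 2-fold), skin genes 2.96 and B and plasma cell genes 0.70 (1 of 12 by 2-fold), whereas CD8 genes were at -0.50 (2 of 14 lower), interferon gamma genes at -0.20 and macrophage genes at -0.33, each standing apart. Muscle genes did not differ as a list (0.04, percentile 41.6). Against DC101 alone, 1546 genes were higher and 1990 lower, with CD8 genes 0.89 (6 of 14), T cell receptor genes 1.32 (12 of 13) and B and plasma cell genes 2.03 higher (11 of 12), epithelial genes at -3.55 and skeletal muscle genes 2.28 higher. The median of all genes was -0.09 in this pair and moved by 0.20 under median-of-ratios scaling.

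**Figure D3:**
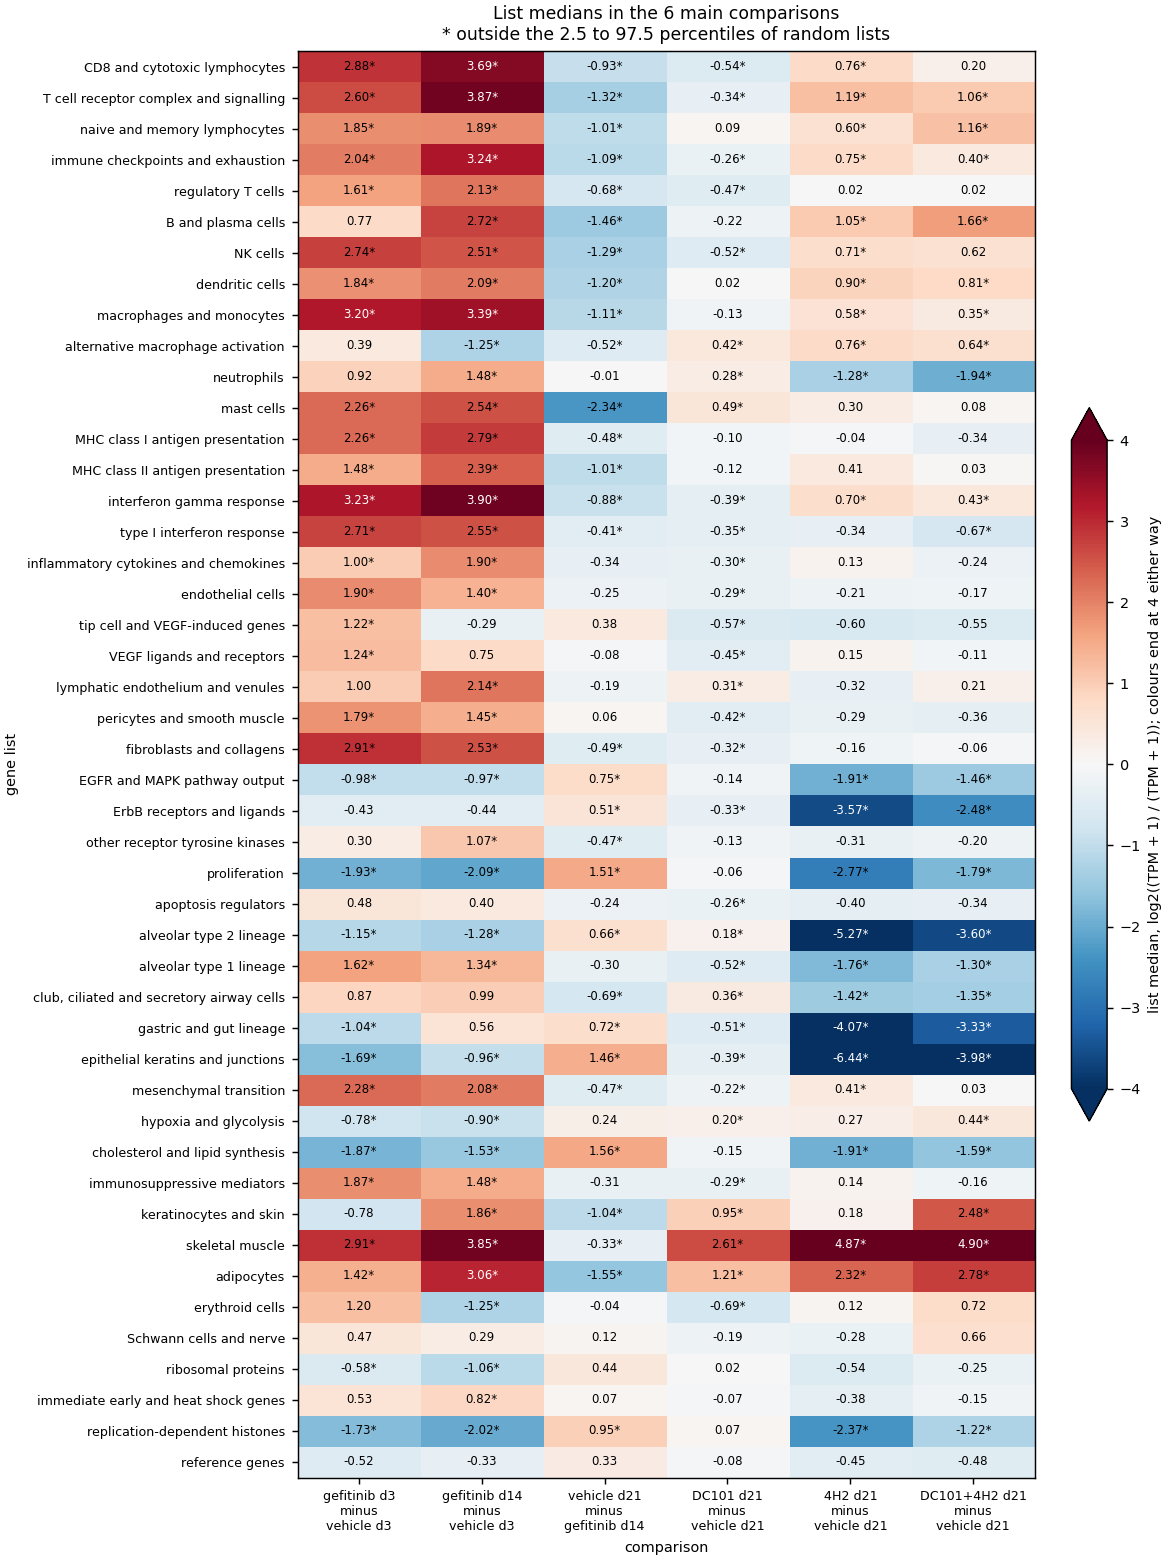
Median log2((TPM + 1) / (TPM + 1)) of each of 46 gene lists (y axis) in the 6 main comparisons (x axis), with colour for the value and an asterisk where the list stood apart from random lists. Across the 6 comparisons, 95 medians stood apart upward and 85 downward.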

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

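All tests in this part were chosen after the result was seen. Among the gene lists that stood apart in both comparisons, 9 had medians of opposite sign with DC101 and with 4H2, each against the same vehicle library of day 21. The sign of each median, and the gap between medians, depends on that shared library. With 1 library per group the difference itself was not tested. The 4H2 median exceeded the DC101 median by 1.31 for CD8 and cytotoxic genes (0.76 against -0.54), 1.53 for T cell receptor genes (1.19 against -0.34), 1.02 for checkpoint genes, 1.23 for NK cell genes, 1.09 for interferon gamma genes and 0.62 for mesenchymal transition genes. The difference was -1.57 for neutrophil genes, -5.45 for alveolar type 2 genes and -1.78 for club, ciliated and secretory airway genes. Neutrophil genes went both ways with 4H2, 4 of 7 being lower and 2 higher by 2-fold. In 2 of these lists the signs were not opposite under every setting: neutrophil genes with DC101 were at -0.31 with a mean TPM of at least 5, and the mean of mesenchymal transition genes with 4H2 was -0.014.

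Epithelial genes were lower in the 4H2 and combination libraries, where skeletal muscle genes were higher. Dilution of the tumor by muscle RNA would lower every other cell type by about as much. Yet the epithelial median lay -6.28 from the fibroblast median with 4H2 and -3.91 with the combination. This argues against dilution by muscle RNA alone, but not against host tissue that brings its own fibroblasts. Specimens that held host tissue in place of tumor stay open: the muscle median was 4.87 with 4H2. A tumor shrunken by the antibody may look the same, so treatment response and sampling cannot be told apart in this design. The response to 4H2 is therefore an untested hypothesis.

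T cell receptor genes were higher in the 4H2 library. If the loss of epithelial RNA had only raised all other cells, fibroblast genes would have been as high, but the T cell median lay 1.35 above theirs. More leukocytes of every kind would have raised macrophage genes alike, and the T cell median lay 0.60 above the macrophage median, with non-overlapping quartiles in both cases. The difference was not particular to T cells: B and plasma cell genes were at 1.05, dendritic cell genes at 0.90, CD8 genes at 0.76, inside the macrophage quartiles of 0.35 to 0.95, and regulatory T cell genes at 0.02. An uneven shift among leukocytes with 4H2 may remain as a hypothesis, found and tested on the same libraries, and leukocytes of host tissue around the tumor were not tested as a source.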

How the results depend on the processing

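Sequencing depth is unknown and no group has a replicate, so neither counting error nor animal variation limits these values in a known way. No paired analysis was possible because each group has 1 library and no test was made. Alternatives that left out or rescaled without genes following muscle were chosen after seeing the data. The 12 counts of genes at least 2-fold apart were recomputed under the alternatives. Of the recomputed counts, 68 stayed within 1.5 times the main count and 10 did not. The 68 include the lower counts of the antibody comparisons without genes that follow muscle, which that selection all but fixed in advance. With a pseudocount of 5, which shrinks low genes by construction, the higher counts were 1924 and 2073 at days 3 and 14 of gefitinib, 674 after gefitinib (lower count 538), 203 with DC101 (lower 51) and 1012 with 4H2. The lower count with DC101 was 296 with a pseudocount of 0.1 and 93 with a mean TPM of at least 5, and its higher count was 216 without genes that follow muscle, fewer genes being counted. The 16 medians of lists named in advance for a comparison, counted over settings, kept direction and call in 132 cases. The endothelial list of the combination, which did not stand apart, turned from -0.17 to 0.06 under median-of-ratios scaling and 0.07 rescaled without genes that follow muscle. The interferon gamma list of the combination did not stand apart as a mean (0.43), and the cause was not tested. The 166 medians of other lists that stood apart were likewise counted over settings. Direction and call were kept in 1325 cases, direction only in 59, and 6 cases reversed. With DC101, neutrophils were at -0.31 and VEGF ligands and receptors, at -0.45 in the main setting, at 0.13 with a mean TPM of at least 5, the latter at 0.32 without members of other lists, and mast cells at -0.006 without a filter. With 4H2, the means of alternative macrophage activation and mesenchymal transition were -0.063 and -0.014. The cause was not tested. Over all 276 list medians, 13 turned sign under a rescaling, none of them of a list that stood apart. Counted over genes and settings, 456 single gene values were little moved and 115 moved. This check covered only the 8 highest, 8 lowest and fixed genes of each main comparison, 143 entries in the main setting. None of these at least 2-fold apart changed direction. A pseudocount cannot change a direction, and each rescaled value stayed within 1.5-fold of the main one. The outcome therefore says little about other genes, and smaller differences were not checked for direction.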

Other observations

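All tests in this part were chosen after the result was seen, and so were the genes Nos2, Arg1, Ccl19, Cxcl13, Cd4, Mcpt4 and Cma1. Arg1 and Nos2 encode enzymes that compete for arginine in macrophages. Arg1 was at 142.4 TPM in the day 3 vehicle library, 77.2 and 27.4 at days 3 and 14 of gefitinib, 18 in the day 21 vehicle library, 18.5 with DC101, 1.2 with 4H2 and 2.4 with the combination. Nos2 was at 4.1, 10.5, 18, 9.7, 8.5, 106 and 70.8 TPM in that order. The alternative activation list did not follow Arg1 with 4H2. Against vehicle at day 21 its median was 0.76 (percentile 99.3, 3 of 10 higher and 3 lower by 2-fold) and its mean -0.063. Ccl19, a chemokine gene of lymphoid stroma, was at 0.7 TPM in the day 21 vehicle library, 2.8 with DC101, 43.7 with 4H2 and 92.9 with the combination, and Cxcl13, which draws B cells, at 8.5, 8.3, 14.6 and 27.8 TPM. Cd4 was at 31.4, 31.1, 84.2 and 64.2 TPM in those libraries.

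Against the day 3 vehicle library, the mast cell list had medians of 2.26 (5 of 7 higher, 1 lower) and 2.54 (6 of 7 higher, 1 lower) at days 3 and 14 of gefitinib. Of the mast cell protease genes, Mcpt4 was at 2.8 TPM in the day 3 vehicle library, 21.3 and 41.5 at days 3 and 14 of gefitinib and 7.4 in the day 21 vehicle library, and Cma1 at 4, 31.8, 28 and 4 TPM. The 58 hair genes added up to 11.3 TPM in the day 3 vehicle library, 1.1 and 194.5 at days 3 and 14 of gefitinib, 3.8 in the day 21 vehicle library, 61.3 with DC101, 24.3 with 4H2 and 1208 with the combination.

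At day 3 of gefitinib, EGFR and MAPK output genes were lower and alveolar type 1 genes higher than in vehicle. A smaller share of epithelial cells would lower alveolar type 1 genes too, but their median lay 3.31 above the epithelial median, which argues against it for these genes. For MAPK output, which lay 0.71 above the epithelial median, a smaller share and lower signalling cannot be told apart, because Egfr, alveolar type 2 and epithelial genes give different gauges of that share. Expression of alveolar type 1 genes by stromal cells stays open as well: their median lay -1.60 from the fibroblast median in the 4H2 library, with overlapping quartiles. A shift of surviving tumor cells toward type 1 expression may be a candidate explanation, and it was not tested.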
